A study of Mus musculus with 3 samples.

How the data were processed

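Single-cell RNA was measured in islets of Langerhans isolated from mice carrying Ngn3-CreERT and R26-CAG-TdTomato, 10 days after tamoxifen. Ngn3 is another name of Neurog3. In such mice a Cre recombinase driven from Neurog3 is switched on by tamoxifen and removes a stop sequence at the ROSA26 locus, so that cells active for the driver, and their descendants, make the red protein TdTomato. The labels give 6 mice and 3 samples, all in 1 group, with 2 mice pooled in each of replicates 2 and 3. About 10000 cells were loaded per channel of the 10x Genomics 3-prime system, with 11 and 12 PCR cycles. There is no untreated or Cre-negative sample.

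The authors deposited a table of raw UMI counts (unit: counts) for replicate 1, called library 1 here, made per the labels with Cell Ranger 3.2.0, cutadapt 2.5 and FastQC 0.11.8 on the mm10 build. Replicates 2 and 3 were deposited in 1 joint table without a header, made per the labels with Cell Ranger 5.0.0, cutadapt 2.5, FastQC 0.11.8 and Seurat 4.0.0 on the same build. The values of the joint table, as the authors deposited them, are the natural log (unit: ln) of 1 plus 10000 times the UMI count over the total of the cell. The unit was checked on the values: after the exponential minus 1, each column summed to 10000, and 100% of 35558086 nonzero values were whole multiples of the smallest value of their cell within a tolerance of 0.001. Whole UMI counts were therefore recovered for the joint table.

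The joint table has 16050 columns with 4 barcode suffixes, and 3008 columns under 1 suffix repeat another suffix exactly. The repeats were dropped, which left 13042 distinct cells in 3 barcode blocks of 5894, 3008 and 4140 cells. No label ties a suffix to a sample, so replicates 2 and 3 could not be told apart and the joint table counts as 1 library. All tests therefore have n = 2 libraries, and the barcode blocks are used only for values and directions, not as replicates. The labels put 2 samples in the joint table, and why it holds 3 distinct blocks was not settled. Barcodes were compared among its suffixes and not with library 1. That the 2 libraries share no cells thus rests on the labels. The tables differ in software version and gene set as well as in mice: library 1 lists 16157 genes and the joint table lists 32285, with 15741 in common.

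Cells were kept with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs. Doublets were scored with Scrublet in scanpy 1.11.5 (Python 3.11.15) per barcode block. The automatic threshold called 9 cells in library 1 and 3, 33 and 0 in the blocks. After these counts were seen it was replaced by removing the highest scores at 0.8% per 1000 cells, which removed 6 cells in library 1 and 217, 54 and 106 in the blocks. Cells of each table were clustered on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (igraph implementation in scanpy, seed 0). Neurog3, the TdTomato row and 304 genes of 12 fixed lists were kept out of the variable genes, so that classes could be compared on them. A cluster took the class with the most markers among its 10 leading genes where these held at least 2, and otherwise the class whose markers had the highest mean level over the lowest cluster. By the second part, beta clusters of 97 cells in library 1 and of 1186, 33 and 35 cells in the joint table were named with no beta marker among their leading genes. Endocrine clusters with at least 2 markers of another endocrine class among the leading genes were set aside as mixed, as were clusters not named beta whose median insulin UMIs exceeded 5 times those of non-endocrine cells. The naming rule, with the insulin limit, was revised 2 times after the clusters were seen, because earlier versions put clusters under markers they lacked.

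Shares of cells with a UMI have exact Clopper-Pearson intervals and summed UMIs scaled to the usual CPM exact Poisson intervals, both at 95%. A count of 0 among unthinned cells is given with the share that 3 counts would make, which lies below the upper end of the exact interval, and a count of 0 after thinning with the exact interval. Intervals and limits cover counting error only. Shares were also taken after thinning each cell to 2000 UMIs. A hormone was counted in a cell above 5 times the median of non-endocrine cells of its table plus 5 UMIs. This threshold was set after the data were seen. The first choice, the 99th percentile of non-endocrine cells, was replaced because a few such cells rich in hormone RNA raised it in the joint table.

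Classes and marked cells were compared with limma 3.58.1 (R 4.3.3) on log2 of the mean count per 10000 UMIs plus 0.05, for each class or side of each table, with the library as a block and moderated variances with a trend. Genes needed 0.1 per 10000 in at least 2 columns, and columns were centred on their median. Benjamini-Hochberg adjusted p under 0.05 over all genes tested was the threshold. The plan written before the data were examined used edgeR on counts. The log scale of the joint table led to limma, and edgeR 4.0.16 on the recovered counts became an alternative. The pseudocount makes fold changes of rare genes smaller than edgeR's. Beta, alpha and delta cells, the endocrine classes with at least 10 cells in both tables, were fitted together, which leaves 2 residual degrees of freedom per gene. The fit of delta cells with against those without a Neurog3 UMI leaves 1, so its SEs and p-values rest mostly on variance shared over genes. Gene lists were tested with camera, with preset and with estimated correlation. Comparisons possible in the joint table alone are given as values, with no test.

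Before the data were examined, the gene lists, markers, comparisons and a rule for naming genes were written down. The rule names Neurog3, the reporter and the hormone genes. It adds the 10 largest rises and the 10 largest falls among genes past the threshold, with the same direction in every library and at least 10 UMIs on the higher side, and up to 10 list members past the threshold. Between delta and beta cells it was applied only to genes kept out of clustering, since the others helped to define the classes. In comparisons made in the joint table alone, which have no threshold to pass, the rule was replaced after the data were seen by the 5 largest matched differences each way among genes above 0.5 per 10000 on 1 side with 1 direction in every block.

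The fits were tested on simulated data, made by thinning the counts of 100 genes each 2-fold and 4-fold on 1 side. These genes were drawn only from those with many UMIs in delta cells without a Neurog3 UMI. Recovery of rarer genes, among them several named below, was not measured. For delta against beta cells limma recovered 81% and 100% of them with 4 false calls, and edgeR 85% and 100% with 5. For delta cells with against without a Neurog3 UMI limma recovered 59% and 99% with 12 false calls, and edgeR 93% and 100% with 15. Alternatives tried were edgeR with its own and with DESeq2 factors, DESeq2 1.42.0, other pseudocounts of 0.01 and 0.2, no filter, no centring, no block, doublets kept, Leiden resolution 0.5, joint clustering, cells matched on depth, cells with a single hormone, and leaving out each table. Gene positions are from the GENCODE annotation of the same build.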

Results

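RNA of single islet cells was counted in 3 samples from lineage-traced mice, all in 1 group. Library 1 (replicate 1) holds 1146 cells with 27474046 UMIs and a median of 18140 UMIs per cell. The joint table (replicates 2 and 3) holds 13042 distinct cells with 196833349 UMIs and a median of 13099.5 per cell. Its 3 barcode blocks hold 91385979, 45329534 and 60117836 UMIs. Mitochondrial UMIs exceeded 20% in 255 cells of library 1 and in 0 of the joint table. The series title asks about cells that express Neurog3 in the adult pancreas, so each comparison below asks which islet cells carry its transcript, which carry the reporter, and what sets them apart. Values are given per table, since only 2 libraries could be formed.

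After filtering, 853 cells of library 1 and 11072 of the joint table remained. Beta cells, which make insulin, were 52.1% of library 1 (48.6% to 55.5%) and 57.4% of the joint table (56.5% to 58.3%). Alpha cells, which make glucagon, were 12.5% and 9.33%. Delta cells, which make somatostatin, were 76 cells or 8.91% of library 1 (7.08% to 11.0%) and 459 cells or 4.15% of the joint table (3.78% to 4.53%). Somatostatin RNA was above the hormone threshold in 68 of the 76 and in all 459. At Leiden resolution 0.5 these shares were 14.1% and 9.18%, and with joint clustering 11.7% and 6.67%. In the barcode blocks of the joint table the delta share was 5.11%, 4.15% and 2.77%. A cluster of PP cells, which make pancreatic polypeptide, was found in the joint table alone, with 363 cells or 3.28%. Endothelial cells, macrophages, fibroblasts and pericytes were found in both tables, and Schwann, B and T or NK cells in the joint table. No cluster took the duct class. Mixed clusters held 113 cells of library 1 and 1249 of the joint table.

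Neurog3 (ENSMUSG00000044312.4, chromosome 10, 62133090 to 62134763, plus strand, protein coding) is the transcription factor gene that drives the Cre of these mice. In delta cells, 22 of 76 had at least 1 Neurog3 UMI in library 1, a share of 28.9% (19.1% to 40.5%) at a median of 10200 UMIs per cell. All 22 were among the 68 with somatostatin RNA above background, a share of 32.4% (21.5% to 44.8%). In the joint table, 107 of 459 did, a share of 23.3% (19.5% to 27.5%) at 5740 UMIs per cell. The level in delta cells was 43.2 CPM (30.1 to 60.1) in library 1 and 45.7 CPM (38.2 to 54.3) in the joint table. It was 50.4, 37.8 and 41.6 CPM in the 3 barcode blocks. In beta cells 1 of 444 had a UMI in library 1, which is 0.225% at 38746.5 UMIs per cell, and 53 of 6358 in the joint table, which is 0.834% (0.625% to 1.09%) at 20525 UMIs per cell. The beta level was 0.0545 CPM in library 1 and 0.398 CPM (0.302 to 0.516) in the joint table. In alpha cells it was 0 of 107 in library 1, which allows a share of up to 2.80%, and 5 of 1033 or 0.484% in the joint table. In PP cells it was 13 of 363, a share of 3.58% (1.92% to 6.05%) at 12812 UMIs per cell, with 2.24 CPM (1.19 to 3.83).

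Endothelial, immune, stromal and glial cells, which should lack Neurog3, give the background. In library 1 none of 113 such cells had a UMI, which allows up to 2.65% at a median of 8587 UMIs per cell. In the joint table, 2 of 1610 did, which is 0.124% (0.0150% to 0.448%) and 0.307 CPM (0.0372 to 1.11) at 2898.5 UMIs per cell. The delta share lay far above this background in both tables. The beta share of the joint table lay above the background share, but beta cells were deeper, and the beta CPM lay within the background interval. Thinned to 2000 UMIs, the share was 11.1% (4.92% to 20.7%) of delta cells in library 1 and 10.4% (7.76% to 13.6%) in the joint table. At that depth it was 0.0472% (0.00974% to 0.138%) of beta cells and 0.0807% (0.00204% to 0.449%) of non-endocrine cells of the joint table. A difference between these was not detectable, but CPM and thinning both count insulin in the total of a cell. Median insulin there was 13561.5 UMIs in beta cells, at 20525 UMIs per cell, and 290 in non-endocrine cells, at 2898.5. Thinning thus left beta cells fewer other UMIs, so whether beta cells exceed the background was not decided. The alpha level of 0.540 CPM also lay within the background interval, and the PP interval lay above it. Thinned to 2000 UMIs, 1 of 360 PP cells had a UMI, which is 0.278% (0.00703% to 1.54%) and overlaps the background. The PP levels of barcode blocks 2 and 3 overlapped it too, at 2.66 CPM (0.549 to 7.79) and 0.876 CPM (0.106 to 3.16), and that of block 1, at 3.33 CPM (1.44 to 6.56), overlapped the non-endocrine interval of its own block (0.0803 to 2.40). The CPM of PP cells over the joint table thus lay just above background, but PP cells were not separated from it at equal depth or within blocks. With few Neurog3 UMIs left after thinning or in each block, these checks could not decide whether PP cells exceed background.

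**Figure D1:**
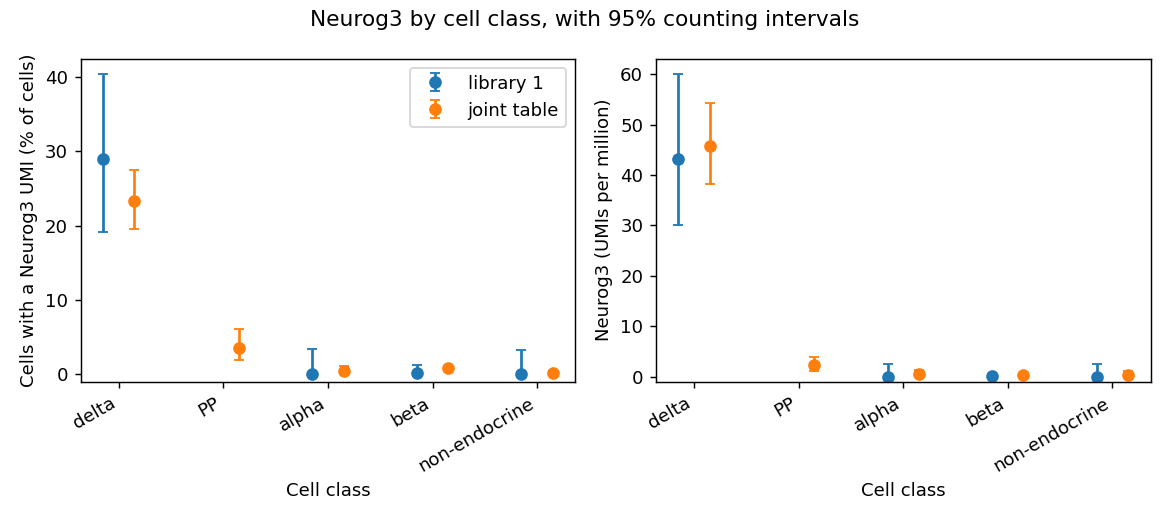
Cells with a Neurog3 UMI (left, % of cells) and Neurog3 level (right, UMI counts scaled as CPM) by cell class. Points are class values in library 1 and the joint table, and bars are exact 95% counting intervals. Delta cells lie at 28.9% and 23.3%, and PP cells, found in the joint table alone, at 3.58%.

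In the limma fit of beta, alpha and delta cells over the 2 libraries, Neurog3 was higher in delta than in beta cells by 2.28 log2 units (SE 0.22, adjusted p 6.97e-05), with 2.19 in library 1 and 2.38 in the joint table. The blocks gave 2.58, 2.01 and 2.20. Against the mean of beta and alpha cells the delta value was 2.63 (SE 0.19, adjusted p 1.41e-05). Beta cells lay below the mean of the others by −0.80 (SE 0.19, adjusted p 0.0126) and alpha cells by −1.83 (SE 0.19, adjusted p 1.33e-04). Both contrasts hold delta cells in that mean. Their gap does not show less Neurog3 in alpha than in beta cells, since centring moved these classes apart. The column medians it removed were −0.50 and −0.56 in beta and 0.20 and 0.10 in alpha cells. In the joint table the alpha CPM was the higher one. Because 0.05 was added before the log, the fold changes are small: edgeR on UMI counts gave 5.89 for delta against beta (adjusted p 2.97e-08), and over 11 alternatives the value ran from 1.08 to 6.24 with adjusted p from 3.53e-25 to 0.00144. The CPM of beta and alpha cells, with insulin counted in the total, is at or near background. The size of the fold change is therefore not well determined.

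Seen from all cells with a Neurog3 UMI, 22 of 33 in library 1 were in the delta cluster, 10 in mixed clusters and 1 among beta cells. In the joint table, of 290 such cells, 107 were delta, 110 mixed, 53 beta, 13 PP and 5 alpha cells. Somatostatin (Sst, chromosome 16, 23889573 to 23890958) was above background in 32 of the 33, which is 97.0% (84.2% to 99.9%), and in 231 of the 290, which is 79.7% (74.6% to 84.1%). Among beta cells of the joint table, the 158 with Sst above background had 2.65 CPM of Neurog3 (1.41 to 4.53) and the other 6200 had 0.318 CPM (0.231 to 0.427).

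The reporter was examined next, as the row named TdTomato. In library 1 it held 16 UMIs in 15 cells. Of these, 7 were among 444 beta cells (1.58%, 0.636% to 3.22%), 2 among 107 alpha cells (1.87%), 2 among 76 delta cells (2.63%, 0.320% to 9.18%) and 4 among 113 cells of mixed clusters. None of 113 non-endocrine cells had one, which allows up to 2.65%. The level was 0.436 CPM (0.188 to 0.859) in beta cells and 2.47 CPM (0.299 to 8.92) in delta cells, with overlapping intervals. A difference between classes was not detectable at this depth.

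In the joint table the row named TdTomato had UMIs in every class: 38.3% of beta, 31.7% of alpha, 22.2% of delta, 34.4% of PP and 18.2% of non-endocrine cells. Its level was 23.5 CPM (22.7 to 24.3) in beta, 43.9 CPM in alpha, 39.4 CPM (32.4 to 47.4) in delta, 68.8 CPM (59.9 to 78.7) in endothelial cells, and 58.0 CPM (52.3 to 64.2) in all non-endocrine cells. CPM counts insulin in the total of a cell, which lowers the values of beta cells most. Within the blocks the non-endocrine level was 59.0, 58.1 and 56.4 CPM and the beta level 22.8, 23.4 and 24.5 CPM. The row lies at position 10567 of 32285, between Thumpd3 and Setd5. The annotation places there the gene Gt(ROSA)26Sor (ENSMUSG00000086429.9, chromosome 6, 113067428 to 113077333, minus strand, antisense type), and the joint table has no row of that name. Library 1 has both names, with TdTomato as the last row. Over the 7 cell classes found in both tables and the mixed clusters, the joint row was 0.645 to 1.27 times the library 1 level of Gt(ROSA)26Sor. Over the 3 cell classes with a TdTomato UMI in library 1 and the mixed clusters, it was 15.9 to 53.8 times the library 1 level of TdTomato. The rows named TdTomato in the 2 tables thus measured unlike amounts.

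**Figure D2:**
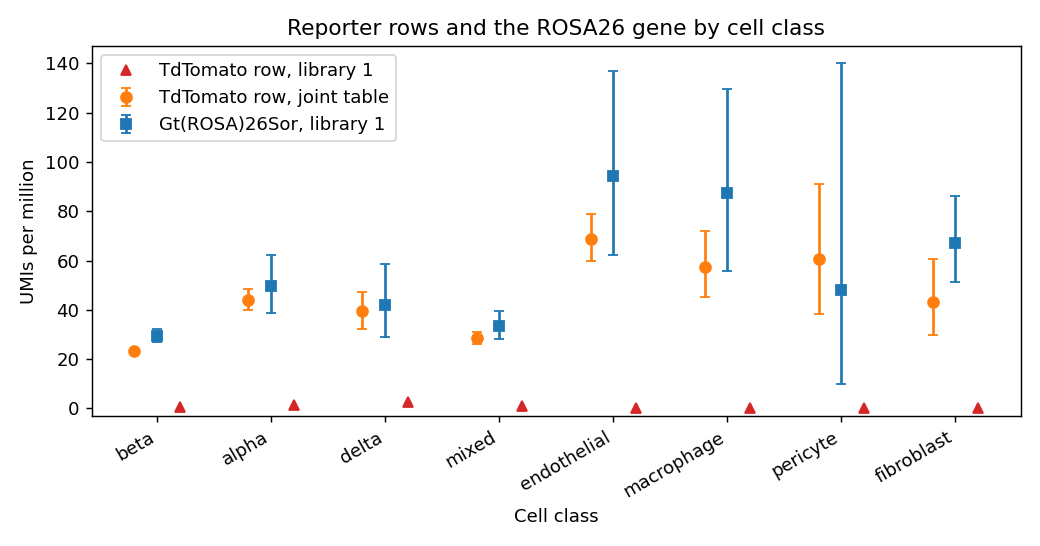
UMI counts scaled as CPM (vertical axis) of the row named TdTomato in the joint table and of Gt(ROSA)26Sor and TdTomato in library 1, for the cell classes found in both tables and the mixed clusters. Points are class values and bars exact 95% counting intervals, drawn for the first 2 series. The joint row lies at 0.645 to 1.27 times the ROSA26 gene, while the library 1 reporter reaches 2.47 CPM at most.

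The limma test of the row named TdTomato over both tables gave −0.33 log2 units for delta against beta cells (SE 0.22, adjusted p 0.327), and 0.04 with no filter on low values. EdgeR on UMI counts, the tool of the first plan, gave −0.48 (adjusted p 0.0520). Without median centring it was 0.58, past the threshold (adjusted p 0.0341, in a range of 0.0341 to 0.962 over 11 alternatives). The other contrasts had adjusted p of 0.400 for delta, 0.407 for beta and 1.0 for alpha cells against the mean of the other classes. No difference between classes held up, and the test mixes rows that measured unlike amounts.

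Cells with and without a UMI of this row could be compared within a class in the joint table alone, as values with no test. Library 1 had 2 such delta cells, 7 beta and 2 alpha cells, fewer than the 10 required. Of the delta cells of the joint table, 102 had a UMI of the row and 357 had none. Neurog3 was found in 22 of the 102, which is 21.6% (14.0% to 30.8%), and in 85 of the 357, which is 23.8% (19.5% to 28.6%). The log2 difference of Neurog3 was −0.53 in delta cells, and the CPM intervals overlapped (23.4 to 52.5 with, 40.1 to 59.5 without). In 2434 beta cells against 3924 it was −0.04, and in 327 alpha cells against 706 it was −0.09. After matching on depth, the largest differences among genes with 1 direction in all blocks were Ormdl2 at 1.63 and Tspan2 at −1.03 in delta cells, Hsph1 at 0.19 and Ppy at −0.66 in beta cells, and Gadd45g at 0.58 and Supt5 at −0.43 in alpha cells. Gcg in beta cells, at 0.79, and Sst in alpha cells, at 0.73, differed by more but changed direction between blocks.

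Delta cells with a Neurog3 UMI were compared with the other delta cells to ask which genes accompany the transcript: 22 against 54 cells in library 1 and 107 against 352 in the joint table. The 54 include 8 cells with Sst at background and a median of 3043.5 UMIs. Their part in the differences of library 1 was not tested separately. In limma 20 of 8370 genes passed the threshold, 3 higher and 17 lower, and 419 had an unadjusted p under 0.05. With edgeR 1 gene passed, with edgeR under DESeq2 factors 0 (226 at an unadjusted p under 0.05), and with DESeq2 1, which was not among the 20. The genes higher in limma were Cyp4v3 by 1.44 (SE 0.36, adjusted p 0.0312), Ttr by 0.76 (SE 0.16, adjusted p 0.00189) and Gcg by 0.73 (SE 0.14, adjusted p 1.58e-04). Gcg moved in opposite directions in the tables, −0.07 in library 1 and 1.54 in the joint table. With 1 residual degree of freedom, the SEs and p-values of this fit rest mostly on variance shared over genes. They do not measure how far the 2 tables lie apart. The largest falls were Apoe at −4.88, Cd9 at −2.85, Cd74 at −2.52, Npy at −2.23, Rfxank at −2.11, Zfp36l1 at −1.94, Spp1 at −1.84, Dbi at −1.76, Bst2 at −1.73 and Pnlip at −1.61. Apoe, the gene with the lowest adjusted p (1.37e-30), fell by 8.27 in library 1 and 1.5 in the joint table, but rose by 0.77 in barcode block 2. Cd9 and Spp1 also rose in barcode block 2, by 0.24 and 0.61, and in barcode block 3, by 1.02 and 0.23.

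Few cells carried several of these falls. In library 1 a single delta cell without Neurog3 held 353 of 393 Spp1 UMIs, and a single cell held 5 of 5 Npy UMIs. Apoe was found in 11 of the 76 cells, and 1 cell held 35.8% of its UMIs. Ins1 and Ins2 fell by 0.76 and 0.75 (adjusted p 6.17e-05 and 3.69e-04 in limma), and 1 cell of library 1 without Neurog3 held 51.8% and 53.4% of their UMIs. In the joint table the falls of Ins1 and Ins2 were −0.11 and −0.09. Sst differed by 0.17 (SE 0.16, adjusted p 0.998) and Ppy by −0.34 (SE 0.14, adjusted p 0.791), neither past the threshold.

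The 12 fixed lists were tested in the same fit, and none passed camera: the lowest adjusted p was 0.596 with preset and 0.956 with estimated correlation. Over all genes tested, 3 list members passed, Ins1 and Ins2 of the beta-maturity list and Npy of the beta-immaturity list, all lower. Adjusted over the list alone, Gadd45a of the endocrine progenitor list and Hes1 of the Notch list were lower too, by −2.01 and −1.39. The progenitor list had a median of 0.04 over 19 genes and a mean of −0.10, and the Notch list a median of 0.06 over 5 genes and a mean of −0.17.

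Beta cells with a Neurog3 UMI could be compared in the joint table alone, 53 against 6305, since library 1 had 1. Sst was higher by 5.27 log2 units, 64.6 against 1.38 per 10000, and by 4.56, 5.6 and 5.74 in the blocks. Only 11 of the 53 had Sst above background, and after leaving out cells with a strong second hormone the difference was 2.66. Gcg and Ppy did not keep 1 direction: Gcg was higher by 2.54, with 0.30, 4.77 and −1.19 in the blocks, and Ppy by 0.09, with −0.75, 0.60 and −0.15, while in depth-matched cells they were higher by 3.11 and 3.21. Of the 53, 6 came from a cluster of 35 beta cells led by Stmn1 and the cell-cycle gene Top2a, and 5 of these 6 had Sst above background. In depth-matched cells Rbp4 was higher by 3.80, Cd24a by 3.77, Stmn1 by 3.76 and Arg1 by 3.59. Ins1 was lower by −0.47, Ins2 by −0.43, Cox6a2 by −1.21, Rasd1 by −1.07, Gadd45gip1 by −0.98, Sh3pxd2a by −0.94 and Sytl4 by −0.90. These are values with no test.

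Delta and beta cells were compared over the fixed lists, for the genes that took no part in clustering. Of 237 such genes, 158 passed the threshold in limma, 110 higher and 48 lower in delta cells, and all 158 moved the same way in both tables. Centring matters here: the column medians lay at −0.50 and −0.56 log2 units for beta cells and at 0.43 and 0.34 for delta cells in library 1 and the joint table. Without centring the split was 180 higher and 12 lower. Over all 8302 genes it was 1104 higher and 952 lower with centring and 6572 and 209 without. The changes below are relative to the median gene.

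The largest rises were Arg1 by 5.30 (SE 0.21, adjusted p 3.42e-07), Ptprz1 by 4.07, Ffar4 by 2.93, Neurog3, Cd81 by 2.27, Rgs2 by 2.25, Atf3 by 2.00, Fev by 1.84, Ier2 by 1.77 and Klf6 by 1.49. Fev, a transcription factor of endocrine progenitors, had a standard error of 0.23 and an adjusted p of 3.37e-04, with 1.51 in library 1 and 2.18 in the joint table. Atf3 was higher by 3.26 in library 1 and 0.75 in the joint table, and lower by −0.55 in barcode block 3. The largest falls were Papss2 at −4.18, Prlr at −4.18, Ero1lb at −4.14, Trpm5 at −3.61, Sytl4 at −3.59, Slc30a8 at −3.58 (SE 0.12, adjusted p 1.66e-07), Pcsk1 at −2.57, Galr1 at −2.43, Asns at −2.37 and Glp1r at −1.84. All of these kept their direction without centring, which raises every value of delta against beta cells and so could turn only the falls. Several come from the delta-function or beta-maturity lists, whose genes were chosen for these classes and give no independent result. The call of Glp1r was lost in 4 of 11 alternatives, among them no centring (−0.93) and no filter (−1.47), with adjusted p up to 0.578. Those of Atf3 and Ier2 were lost without the replicate block (adjusted p 0.289 and 0.0620, each the highest of 11 alternatives).

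**Figure D3:**
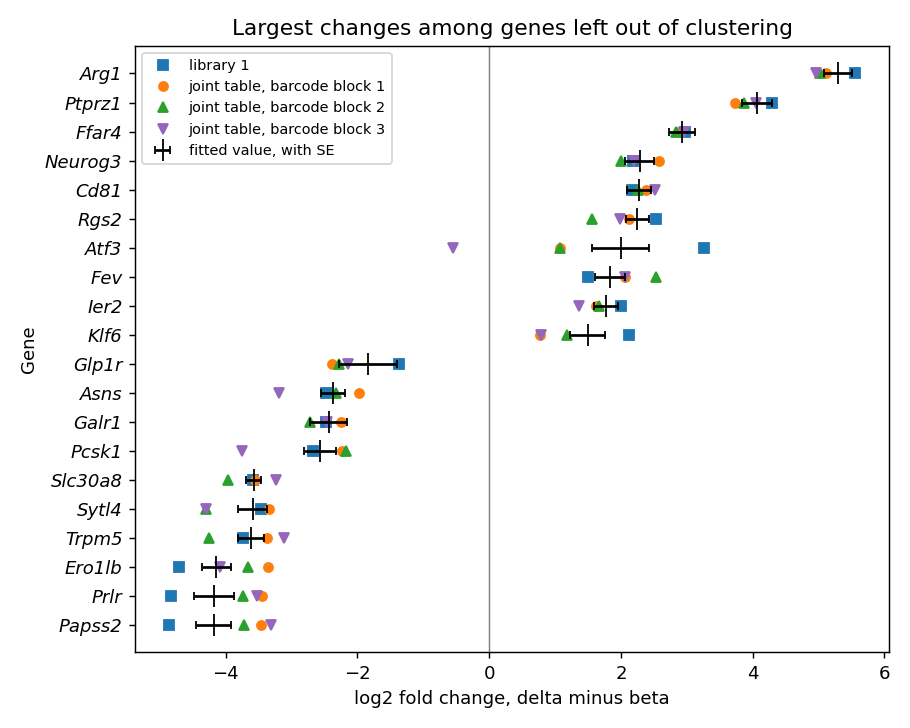
Fitted log2 fold change of delta minus beta cells (horizontal axis, relative to the median gene) for the 10 largest rises and falls among genes kept out of clustering. Vertical ticks with bars are the limma values over 2 libraries with SE, and coloured points are library 1 and the 3 barcode blocks of the joint table. Arg1 lies at 5.30 and Papss2 at −4.18, and Atf3 alone changes sign, in barcode block 3.

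By list, beta-maturity genes were lower in delta cells, 11 of 13 past the threshold (median −2.57) and 11 when adjusted over the list alone. Delta-function genes were higher, 5 against 1 lower of 8 (median 1.85), and 5 against 2 over the list alone. The genes of these lists were chosen for the classes compared, so their direction follows from the class names and is no independent result. Ribosomal protein genes were higher, 74 against 1 lower of 86 (median 0.83), and 77 against 1 over the list alone. Immediate early genes were higher, 14 of 20 (median 1.12), and 15 over the list alone. Those 4 lists kept their direction without centring. That setting raises every value of delta against beta cells, so it could turn only the beta-maturity list. Genes of the unfolded protein response were lower, 15 against 1 higher of 23 (median −0.60), and 16 over the list alone, but without centring 9 were higher and 3 lower (median 0.31). Genes of the mitochondrial genome were lower, 8 of 13 (median −0.75), and 10 over the list alone, but without centring the median was 0.16. In camera, with preset correlation in limma, these 6 lists had adjusted p of 5.88e-09, 0.00287, 1.56e-21, 6.90e-06, 6.53e-06 and 3.16e-05 in that order, and none of these calls held with an estimated correlation (lowest 0.276). Without centring the calls of the delta-function and immediate early lists were lost with the preset correlation too (adjusted p 0.363 and 0.101).

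In the endocrine progenitor list 4 genes were higher and 6 lower of 19, and 6 and 7 over the list alone, with camera p 0.944 in limma. Higher were Neurog3, Isl1 by 1.28, Fev and Runx1t1 by 1.0, and the lower ones included Neurod1 at −1.02 and Insm1 at −0.45. The median of this list was −0.30 and its mean 0.11, and without centring the median was 0.61, with 12 genes higher and 0 lower, so none of the lower calls was kept. EdgeR gave 5 higher and 9 lower of 20. Secretory granule genes went both ways, 5 higher and 7 lower of 25, and 5 and 8 over the list alone, with a median of −0.26. These counts depend on the processing: edgeR gave 4 higher and 16 lower (median −0.43), and without centring 18 were higher and 1 lower (median 0.65). Oxidative phosphorylation genes had 5 higher of 19, 6 over the list alone, with a median of 0.12, and 19 of 19 higher with a median of 1.03 without centring. In edgeR none of them was higher and 7 were lower, with a median of −0.21. Few genes could be tested in the Notch list (0 of 5 past the threshold, also over the list alone, median 0.40, but 5 of 5 higher and median 1.30 without centring), the beta-immaturity list (1 of 3, Cd81, median −0.07, mean 0.65, and median 0.84 without centring) and the proliferation list (1 of 3, Mcm6, median 0.33, but 3 of 3 higher and median 1.24 without centring). With edgeR, which kept more genes, 7 of the beta-immaturity list were higher and 1 lower with a median of 2.23, 2 of 11 of the Notch list were higher and 1 lower, and 1 of 9 of the proliferation list was higher.

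A second hormone was sought in each class against free hormone RNA, of which non-endocrine cells held a median of 87 insulin UMIs in library 1 and 290 in the joint table. Pancreatic polypeptide RNA (Ppy, chromosome 11, 102099930 to 102101319) was above background in 59 of 76 delta cells of library 1, which is 77.6% (66.6% to 86.4%), and in 387 of 459 of the joint table, which is 84.3% (80.7% to 87.5%). Delta cells had a median of 242 and 172 Ppy UMIs, against 1 in non-endocrine cells of both tables. Ppy was above background in 39.3% and 48.4% of alpha cells, 1.58% and 3.40% of beta cells, and 0 and 1.68% of non-endocrine cells, where 0 of 113 allows up to 2.65%. Glucagon RNA (Gcg) was above background in 10.5% and 5.23% of delta cells and insulin RNA in 3.95% and 0.871%. In non-endocrine cells it was 0 of 113 and 2.55% (1.83% to 3.44%) for Gcg, and 0.885% (0.0224% to 4.83%) and 2.17% (1.52% to 3.01%) for insulin. The intervals of the delta insulin shares (0.822% to 11.1% and 0.238% to 2.22%) and of the Gcg share in the joint table (3.38% to 7.68%) overlap these, and only that of Gcg in library 1 (4.66% to 19.7%) lay clear above. For Gcg in the joint table the overlap was narrow, and it does not show that the shares are alike. With doublets kept, the Gcg share of library 1 was 20.9% (13.1% to 30.7%) and the insulin share in the joint table was 2.17% (1.09% to 3.84%). Of the PP cells of the joint table, 29.8% had insulin RNA, 38.6% Gcg and 16.5% Sst above background, and with doublets kept 41.4%, 49.8% and 16.5%.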

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

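All tests of explanations in this part were chosen after the results they concern were seen.

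Library 1 has a signal outside the comparisons: Gt(ROSA)26Sor, the endogenous gene at the locus that carries the reporter, stood at 34.3 CPM over all cells (32.1 to 36.7). It is listed because this is above the limit that a count of 0 allows, which is no test against background. The joint table has no such row, and its row named TdTomato was found in all cell classes. Against reporter RNA of recombined endocrine cells as the only content of that row, non-endocrine cells held the row at all. In endothelial cells it stood at 68.8 CPM (59.9 to 78.7). Non-endocrine cells had 2.47 times the CPM of beta cells. Since insulin in the total lowers the CPM of beta cells most, that ratio does not show an excess over beta cells. Against free RNA in the droplets, the UMIs per cell differed 4.81-fold between non-endocrine classes of at least 75 cells, from 0.0667 in B cells to 0.320 in fibroblasts, while their median insulin UMIs lay between 281 and 318. A candidate explanation is that the row counts RNA of the endogenous ROSA26 gene, alone or joined with the reporter: the row stayed within 1.55-fold of Gt(ROSA)26Sor of library 1 in each of 7 cell classes and in the mixed clusters, which hold unlike cells in the tables, and it takes that gene's place in the table. A small part of reporter RNA in the row stays open, as does recombination in non-endocrine cells, which was not tested. The design has 1 group and gives no further biological explanation to test.

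Clusters set aside as mixed also held Neurog3. In library 1, 11.1% of a cluster of 54 cells with Sst and insulin had a Neurog3 UMI (4.19% to 22.6%), and in the joint table, 19.8% of a cluster of 540 cells with Sst, Ppy and insulin (16.5% to 23.4%). They are listed because neither cluster enters the comparisons of classes and both shares exceed the limit that a count of 0 allows, which is no test against background. Thinned to 2000 UMIs, 15 of 527 cells of the joint cluster had a UMI, which is 2.85% (1.60% to 4.65%) and above the non-endocrine interval of 0.00204% to 0.449%. In the library 1 cluster 0 of 54 did (0 to 6.60%), so a difference from background was not detectable there at equal total UMIs. That total includes insulin, which had a median of 23209 UMIs in the library 1 cluster before thinning.

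The 540 cells were weighed as doublets, free RNA or cells of their own kind. Random pairing at loading would give 24.8 doublets of delta with beta or PP cells in the joint table, and free hormone RNA alone is argued against for the 54.4% (50.1% to 58.7%) with insulin above 5 times the background, whose median insulin was 12553 UMIs. That median in part restates the choice of cells by this limit, which 0.871% of delta cells exceeded. The other 246 of the 540 cells had 0.988 times the median insulin of the 455 delta cells under the same insulin limit (0.861 to 1.10). Since these cells were chosen by their low insulin, this leaves free RNA open as the source of their insulin and shows no more. Their median was 11728 UMIs per cell against 5740 in delta cells. Their Neurog3 level was 17.8 CPM (13.5 to 22.9) against 45.7 CPM (38.2 to 54.3) in delta cells. The insulin values do not account for these differences. Neurog3 UMIs per cell were 0.942 times those of delta cells (0.738 to 1.20), which is consistent with droplets that hold a whole delta cell and the content of another endocrine cell, joined before loading. Cells that make both hormones would give the same ratio, so that explanation stays open and was not tested.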

How the results depend on the processing

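Among the settings below, joint clustering for the tested comparisons, the other pseudocounts, edgeR on its own factors, no centring, and leaving out delta cells rich in non-endocrine RNA were chosen after the data were seen.

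Neurog3 kept its direction and its side of the threshold in all 4 contrasts under every alternative run. For delta against beta cells, 11 alternatives gave 1.08 to 6.24, and for the contrasts against the mean of the other classes 9 alternatives gave 1.28 to 6.43 in delta, −2.93 to −0.34 in beta and −3.50 to −0.94 in alpha cells. With 1 table left out there is a value and no test: delta against beta 2.19 to 2.38, delta 2.55 to 2.71, beta −0.86 to −0.73 and alpha −1.85 to −1.82. With doublets kept, the Ppy share of delta cells moved within its interval, while the Gcg share of library 1 moved past its own, from 10.5% to 20.9%, as did the insulin and Gcg shares of PP cells, from 29.8% to 41.4% and from 38.6% to 49.8%.

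The row named TdTomato had no settled sign. Delta against beta cells turned from −0.33 to 0.040 with no filter and to 0.58 without centring (adjusted p 0.0341). Delta against the others turned to 0.32 without centring. Beta against the others turned from 0.24 to −0.10 with no filter, to −0.0027 with a pseudocount of 0.01, and to −0.55 without centring (adjusted p 0.0237, in a range of 0.0237 to 0.995 over 9 alternatives). Without centring, beta columns lose their offset by construction. With 1 table left out, delta against beta ran from −0.42 to −0.23, delta from −0.27 to −0.21, beta from 0.07 to 0.42 and alpha from −0.20 to 0.20.

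Of the fixed-list genes between delta and beta cells, 110 were higher and 48 lower. Without centring it was 180 higher and 12 lower, as every delta column gains its offset. The lower genes were 83 with edgeR, 81 with edgeR under DESeq2 factors and 31 with no replicate block. Dropping the replicate block cannot move a fold change here, since both tables hold every class compared, and acts on p alone: Neurog3 in delta against beta cells, at 2.28, had an adjusted p of 9.97e-04 without it, and calls over all genes fell from 2056 to 1356.

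Delta cells with against without a Neurog3 UMI changed most. Against 3 genes higher, there were 0 with no replicate block, a pseudocount of 0.2, edgeR on UMI counts, edgeR under DESeq2 factors, the DESeq2 Wald test, and single-hormone cells. Against 17 lower, there were 0 with no replicate block, 2 with a pseudocount of 0.2, 1 with edgeR, 0 with edgeR under DESeq2 factors, 1 with DESeq2, 2 with joint clustering, 5 in depth-matched cells, 5 in those with edgeR, and 11 in single-hormone cells. List members past the threshold went from 3 to 0 with no replicate block, a pseudocount of 0.2, edgeR, edgeR under DESeq2 factors, DESeq2 and Leiden resolution 0.5, and to 1 with joint clustering. Gcg, at 0.73, ran from −0.075 to 1.54 with 1 table left out. Spp1 turned to 0.15 with joint clustering and to 0.13 without the cells richest in non-endocrine RNA. Apart from the fewer cells of the matched and single-hormone sets, the cause was not tested.

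Sst in beta cells with a Neurog3 UMI moved from 5.27 to 6.72 in depth-matched and 2.66 in single-hormone cells. Neurog3 in delta cells with the TdTomato row moved from −0.53 to −0.81 in single-hormone cells. The delta share of library 1 moved from 8.91% to 14.1% at Leiden resolution 0.5 and 11.7% with joint clustering, and that of the joint table from 4.15% to 4.54% at a minimum of 500 UMIs, 9.18% at resolution 0.5 and 6.67% with joint clustering. The beta share of library 1 moved from 52.1% to 45.7% at a minimum of 3000 UMIs and 56.2% with joint clustering. That of the joint table moved from 57.4% to 41.4% at 3000 UMIs, 53.8% at a mitochondrial limit of 10%, 50.4% with doublets kept and 60.3% with joint clustering. The cause was not tested.

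Depth sets the share of cells with a UMI. Thinned to 2000 UMIs, Neurog3 was in 11.1% and 10.4% of delta and in 0 (0 to 0.844%) and 0.0472% of beta cells of library 1 and the joint table. With at least 2 UMIs it was 10.5% and 4.14% of delta and 0 (of 444) and 0.0472% of beta cells. The TdTomato row, thinned, was in 0 (0 to 4.99%) and 9.31% of delta and 0.230% and 4.98% of beta cells, and with at least 2 UMIs in 0 (of 76) and 1.96% of delta and 0.225% and 11.2% of beta cells.

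Of the values of single named genes, 370 were counted as unchanged, 113 lost the threshold, 45 moved, 1 gained the threshold and 3 reversed. Those counted as unchanged include values that turned sign with neither value past the threshold, as for Sst in delta cells. They also include values with 1 table left out that stayed within 1 SE, which have no test. Not run were replicates 2 and 3 left out singly, tools, filter and block for comparisons in the joint table alone, at least 2 Neurog3 UMIs in delta cells (8 cells in library 1) or beta cells (3 cells), at least 2 UMIs of the TdTomato row in delta cells (9 cells), and contrasts with alpha cells at resolution 0.5 and joint clustering, where alpha cells of at least 1 table fell into mixed clusters. Shares are given per table, so leaving out a table leaves the other's value.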

Other observations

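In this part, the test of chance with random groups of delta cells was chosen after the result was seen, and the test that leaves out cells rich in non-endocrine RNA was written down before its outcome was known.

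The genes that differed between delta cells with and without a Neurog3 UMI, 20 in limma, were weighed against chance and against RNA of other cells. In 20 random splits of delta cells without a Neurog3 UMI, limma called up to 18 genes with a median of 3, while edgeR, which called 1 gene in the real comparison, called at least 1 in 17 splits, so chance and a real difference cannot be told apart with these tools. Leaving out the 5% of delta cells with the most non-endocrine marker UMIs, 4 cells in library 1 and 23 in the joint table, kept 12 of the 20 genes among 14 calls. Spp1 no longer fell. Spp1 and Cd74 count here as markers of duct cells and macrophages, so cells could be left out for holding their RNA. The loss of the Spp1 fall may thus follow from that choice of cells and is no evidence for carried RNA. A few delta cells carrying RNA of macrophages or Schwann cells may still account for part of the list. Apoe, Cd74, Cd9 and Dbi lead clusters of macrophages or Schwann cells here. A biological difference between the cells stays open.

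Among the beta cells of the joint table, a cluster of 35 cells was led by Stmn1, Top2a and Cenpf. In it, 6 cells had a Neurog3 UMI, which is 17.1% (6.56% to 33.6%) and 6.82 CPM (2.5 to 14.9), with 1, 2 and 3 of them in the barcode blocks. The median was 24097 UMIs per cell. Thinned to 2000 UMIs it was 1 of 34, which is 2.94% (0.0744% to 15.3%) and overlaps the non-endocrine interval (0.00204% to 0.449%). With so few cells, thinning could not decide whether the cluster exceeds background, while its CPM interval lay above the non-endocrine one. Sst was above background in 5 of the 6 cells and in 13 of the 35.

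Another cluster among the beta cells held 33 cells led by the interferon-response genes Rsad2 and Ifit1. Mixed clusters of the joint table, which entered no comparison, included 79 insulin-containing cells led by Spp1 and Krt19, and 630 cells led by the acinar genes Clps and Cpa1. Neurog3 was found in 0 of the 79, which allows up to 3.80%, and in 3 of the 630, which is 0.476% (0.0983% to 1.39%) and overlaps the background. In library 1 a mixed cluster of 59 cells led by Ppy and Pyy had Neurog3 in 4 cells, which is 6.78% (1.88% to 16.5%) at a median of 20304 UMIs per cell. After thinning it was 0 of 59 (0 to 6.06%), so a difference from background was not detectable at equal depth.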
